A study of Homo sapiens with 6 samples.

How the data were processed

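Gene expression was measured by RNA sequencing in 6 libraries of AsPC-1 cells, a human pancreatic cancer cell line, 48 h after transfection with a control siRNA (siControl, 3 libraries) or with an siRNA against VCPIP1 (siVCPIP1, 3 libraries). Cells were lysed in Trizol and total RNA was made into libraries for the MGISEQ-2000RS sequencer, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

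The deposited table holds TPM, a length-scaled share of transcripts, per gene symbol, computed by the authors and rounded to 2 decimals, per the file headers and the values themselves. It lists 15832 symbols, and the TPM values of a library sum to 999951 to 999994 over them. The reads were placed on GRCh38.p13, per the submitters' processing notes. The aligner, the counting tool, the annotation, the strand setting and any filter are not given in the sources used here. TPM keeps no record of the number of reads, so the depth of each library is unknown and no counting interval or detection floor is given.

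All 6 columns were used as deposited and matched to samples by name. Genes with a mean of at least 1 TPM over the 6 libraries were tested (10966 genes). A pseudocount of 1 TPM was added and values were taken as log2, so a fold change given as log2 is on the log2(TPM + 1) scale and understates the change of genes with low TPM. Groups were compared with limma 3.58.1 in R 4.3.3 (eBayes with a trend, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A count test was not used because no counts were given. For VCPIP1 and for the mean of the YAP/TAZ-TEAD target genes, a two-sided exact permutation test was added. With 3 libraries against 3, its smallest p is 0.1.

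Before the data were examined, 38 gene lists were fixed, covering the Hippo pathway and YAP/TAZ-TEAD targets, the p97/VCP system, Golgi genes, OTU-family deubiquitinases, cell cycle, stress and inflammatory responses, metabolism, pancreatic cancer subtypes, housekeeping machines, RNA quality and markers of other cell types. Each of the 32 lists with at least 5 tested members was compared with all other genes by camera (limma), with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and adjusted over the 32 lists. The fry test (limma) was run on each list as a self-contained test, against no change rather than against other genes, and its p-values are not used here. The genes named in the text were also set by a rule fixed in advance: VCPIP1 and 14 genes of its pathway context, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 TPM and no overlap between the groups, and up to 4 called members with the largest change from each list, of which only some are named. Members that make up a count of 5 or fewer in a list are named as well, and those, GAPDH, ACTB and B2M were chosen after their values were seen. Part of the result of the NRF2 list is not reported here.

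GC content and length came from 1 protein-coding transcript per gene of GENCODE release 29 (GRCh38), which may not be the annotation the authors used. Values were found for 10856 of the 10966 genes tested (99.0%). After the GC trend had been seen, a corrected fit was added in which each library's smooth trend on GC content and log2 length (natural splines with 5 and 3 degrees of freedom, and their product) was removed before limma. Each gene was also set against its 100 nearest genes in transcript GC, 3' UTR GC, log2 length and siControl level. Where the 3' UTR was under 100 nt, transcript GC took its place. Each list was set against 10000 random lists drawn from the nearest genes of its members. The corrected fit has no term for siControl level or 3' UTR GC, which the matched genes take into account. Corrected list results are therefore to be read beside those of the matched lists, where given.

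The fits were tested on simulated data for the siVCPIP1 against siControl comparison over 10856 genes. Of genes changed by 1 on the log2 scale 32% were recovered, and of those changed by 2 84%, with 5 false calls among 10656 unchanged genes. With a linear GC trend added to all genes, the uncorrected fit made 7620 false calls and the corrected fit 5 among the unchanged genes. The corrected fit recovered 49% and 87% of the changed genes. In all these runs the changed genes were drawn only from those with a siControl level well above the filter, so recovery at low TPM was not measured. The splines remove a linear trend by construction, and noise was drawn independently for each gene. These counts therefore do not measure how well the correction removes the trend of the real data. The planted list was called and 0 of 30 random lists were. That simulation held no GC trend and no correlation between genes, so it does not measure false list calls in the real data.

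Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a filter of at least 5 TPM, median-of-ratios and quantile scaling, eBayes without a trend or with a robust fit, the replicate number as a block, an absolute log2 fold change of at least 1, an estimated inter-gene correlation, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.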

Results

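The series profiled AsPC-1 cells, an established line from the ascites of a patient with pancreatic adenocarcinoma, 48 h after transfection with a control siRNA or an siRNA against VCPIP1. VCPIP1 encodes a deubiquitinating enzyme that binds the ATPase p97/VCP and is needed for Golgi reassembly after mitosis. The series title links VCPIP1 to pancreatic cancer progression and Hippo/YAP signalling, so the comparison asks how the transcriptome, and the Hippo pathway in particular, differs when VCPIP1 is targeted. There were 3 siControl and 3 siVCPIP1 libraries, each with a TPM value for 15832 genes and an unknown read depth.

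The libraries of the 2 groups differed in their whole distribution of TPM. The median TPM over all genes was 6.77 ± 0.63 (SD, n = 3) in siControl and 1.59 ± 0.58 (SD, n = 3) in siVCPIP1, and genes with at least 1 TPM numbered 11284 ± 101 and 8817 ± 746. Genes with a GC content under 45% held 15.7% ± 1.18 of TPM in siControl and 5.13% ± 1.32 in siVCPIP1 (SD, n = 3 each). The ribosomal protein genes of the fixed list held 14.7% ± 0.30 and 18.9% ± 0.26. Across genes, log2(TPM + 1) correlated at r = 0.991 to 0.995 within siControl, 0.982 to 0.997 within siVCPIP1 and 0.806 to 0.908 between the groups. Within siVCPIP1, replicate 3 had a median TPM of 2.26, against 1.26 and 1.24 in replicates 1 and 2. The first principal component held 97.1% of the variance.

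VCPIP1 itself, the targeted gene, was measured at 2.93, 3.06 and 2.24 TPM in the siControl libraries and at 0.12, 0.11 and 0.27 TPM in the siVCPIP1 libraries. Its mean fell from 2.74 ± 0.44 to 0.167 ± 0.090 TPM (SD, n = 3), a log2 fold change of -1.68 (SE 0.13, limma, adjusted p = 2.0e-05), with an exact permutation p of 0.1, the smallest this design allows. The gene lies on chromosome 8 from 66628487 to 66667217 on the minus strand (GRCh38, GENCODE 29), with 3 exons in a 9942-nt transcript whose 3' UTR takes up 6017 nt and whose GC content is 38.6%. VCPIP1 kept 6.08% of its siControl mean, and the 100 genes nearest to it in GC content, 3' UTR GC, length and siControl level kept a median of 9.37%. Of those 100 genes, 24 kept as small a share or a smaller one. After correction for GC content and length, a step added after the data were seen, the VCPIP1 change was 0.26 (limma, adjusted p = 0.066), and -0.52 with a pseudocount of 0.1 (adjusted p = 0.021). It was -0.55 after quantile normalization (adjusted p = 0.00054).

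**Figure D1:**
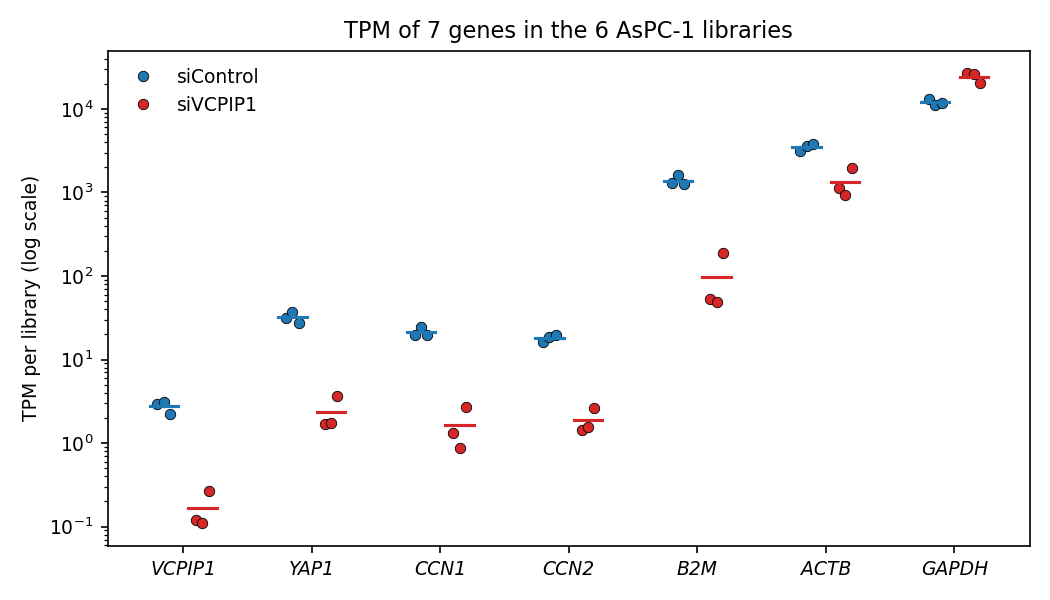
TPM on a log scale (y axis) of 7 genes (x axis) in each of the 3 siControl (blue) and 3 siVCPIP1 (red) libraries, with lines at the group means. VCPIP1, YAP1, CCN1, CCN2, B2M and ACTB lie lower in all 3 siVCPIP1 libraries, and GAPDH lies higher.

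Of 10966 genes tested, 7241 had lower and 1646 had higher TPM in siVCPIP1 (limma, adjusted p under 0.05), and 2079 were not called. The median log2 fold change over all tested genes was -1.12, and 5% of genes lay below -3.20 and 5% above 0.88. The groups did not overlap in 9434 genes (86.0%, against 10% by chance). The balance of directions depended on the scaling: lower genes were 81.5% of those called with TPM as deposited, 52.9% after median-of-ratios scaling (4416 higher, 4951 lower) and 47.9% after quantile normalization (4625 higher, 4258 lower). Both scalings align the centres of the libraries, so a near-even balance follows from the method and is not a separate result. List counts under them are to be read against these gene counts. The median over all genes moved to -0.14 and 0.04 under these scalings, so printed list medians are also set against that of all genes.

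The change in TPM was graded by GC content. Genes were put in 10 bins of equal size by GC content. In the bin with the lowest GC content (up to 39.2%) the median log2 fold change was -2.26 and 98.3% of genes fell, with 0 called higher. In the bin with the highest GC content (from 62.9%) the median was 0.47, and 55.1% of genes rose and 12.3% fell. Across genes, which are not independent replicates, log2 fold change correlated with GC content at r = 0.725 (Spearman's rho 0.737), and GC content and length together accounted for 58.4% of its variance. After correction for both, 4087 genes were called higher and 3419 lower, and 45.6% of called genes were lower. The correction centres each library's deviations at 0, so a near-even balance follows from it. Corrected list counts are to be read against these counts over 10856 genes.

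**Figure D2:**
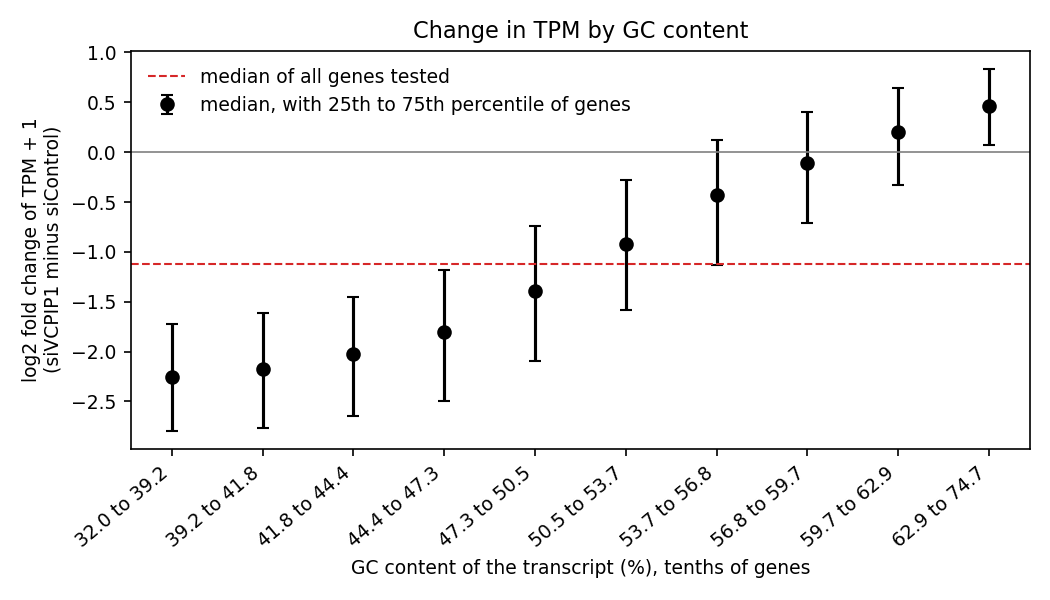
Median log2 fold change of TPM + 1, siVCPIP1 minus siControl (y axis, bars from the 25th to the 75th percentile of genes), in 10 equal bins of the tested genes by transcript GC content in percent (x axis). The median rises from -2.26 in the lowest to 0.47 in the highest bin, and the dashed line marks the median of all tested genes, -1.12.

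YAP/TAZ-TEAD target genes fell further than most genes. Of 19 tested targets, 18 fell and 0 rose, the same counts when adjusted over the list alone. CCN1 and CCN2, the matricellular proteins often used as readouts of YAP activity, fell from 21.3 ± 2.87 to 1.63 ± 0.95 TPM and from 18.04 ± 1.61 to 1.88 ± 0.68 TPM (SD, n = 3). Tissue factor F3 fell from 107.1 ± 21 to 3.06 ± 1.09 TPM, and MYOF, a membrane repair protein, from 96.1 ± 18.01 to 3.82 ± 3.08 TPM. CRIM1 and ASAP1 (log2 fold changes -3.15 and -3.15), the YAP-binding protein AMOTL2 (-2.30), the kinase LATS2 (-2.25) and the receptor tyrosine kinase AXL (-1.56) also fell. Of the 100 genes matched to each target, 10 fell as far as CCN1, 16 as CCN2, 1 as F3 and 2 as MYOF. For CRIM1, ASAP1, AMOTL2, LATS2 and AXL these were 4, 17, 9, 30 and 43. NUAK2 was not called (11.2 ± 2.04 and 8.58 ± 4.09 TPM, adjusted p = 0.22, limma), and its change was 0.69 and 1.06 after median-of-ratios and quantile scaling. ANKRD1, another common readout, lay under the filter, with 1.44 TPM in siControl and 0.087 TPM in siVCPIP1. The list median was -2.70, 1.58 below that of all genes (camera, adjusted p = 0.021), but the adjusted p was 0.95 with an estimated correlation. Median-of-ratios and quantile scaling left 15 and 14 of the 19 lower, with 1 and 3 higher. The list medians were then -1.75 and -1.26, against -0.14 and 0.04 for all genes. The targets' median GC content was 50.3%, and their corrected median was -1.42 with 16 lower and 1 higher (camera, adjusted p = 6.0e-05; 0.61 with an estimated correlation). Of 10000 lists of matched genes, the share with a median as low was 0.0001, the smallest these draws can give (adjusted p = 0.0064 over the lists), and the matched lists had a median of -1.78. The mean of the targets' log2(TPM + 1) was 4.39 ± 0.17 in siControl and 1.92 ± 0.41 in siVCPIP1 (n = 3, exact permutation p = 0.1).

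Of 29 tested Hippo pathway components, 24 fell and 1 rose, with a median of -1.81, 0.69 below that of all genes, and a median GC content of 49.5%. The list did not pass camera (adjusted p = 0.094, and 0.95 with an estimated correlation). Median-of-ratios scaling gave 20 lower and 7 higher, quantile normalization 19 and 6, and GC and length correction 13 and 4 with a median of -0.22. Matched lists had a median of -1.54 (adjusted p = 0.51 over the lists). The transcriptional coactivator YAP1 fell from 32.0 ± 4.64 to 2.37 ± 1.14 TPM (log2 fold change -3.33, SE 0.26, limma, adjusted p = 2.0e-05), and its paralog WWTR1 (TAZ) fell from 16.4 ± 1.96 to 4.29 ± 1.996 TPM. Of the 100 genes matched to YAP1, 28 fell as far, and its corrected change was -1.38 (limma, adjusted p = 6.2e-05). The atypical cadherin FAT1 fell by 3.50, the kinase adaptors MOB1A and SAV1 by 3.27 and 2.96, and the kinase LATS1 by 1.72 on the log2 scale. LATS1, at 3.36 TPM in siControl and 0.323 TPM in siVCPIP1, turned to 0.51 after GC and length correction. It did not turn with that correction and a pseudocount of 0.1. At so low a level the pseudocount of 1 limits the log2 fall, and the correction has no term for level. Of the TEAD transcription factors, the partners of YAP on DNA, TEAD1 fell from 6.90 ± 1.91 to 0.513 ± 0.22 TPM, although its corrected change was -0.03 (limma, adjusted p = 0.88). The same limit bears on that corrected value. TEAD3 fell by 0.79, but lay at 0.33 after median-of-ratios scaling, not called (limma, adjusted p = 0.057), and was higher by 0.65 after quantile normalization (adjusted p = 0.0010). TEAD2 was not called (-0.31, limma, adjusted p = 0.27) and reached 0.84 and 0.97 under these scalings. TEAD4 rose from 134.7 ± 6.80 to 171.7 ± 4.84 TPM (log2 fold change 0.35, limma, adjusted p = 0.020), a call lost after GC and length correction (0.10, adjusted p = 0.37).

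Genes of the p97/VCP system, the Golgi and the OTU family, to which VCPIP1 belongs or is linked, were tested as 3 lists, and none of them passed camera. Of 27 genes tested from the p97/VCP list, 22 fell and 5 rose (UBXN6, UBXN11, ASPSCR1, WDR24 and UBXN1). A place on the list does not by itself make a gene, such as WDR24, a p97/VCP cofactor. The list median was -1.38, 0.26 below that of all genes, at a median GC content of 45.3% (camera, adjusted p = 0.77). VCP fell from 186.1 ± 10.1 to 71.8 ± 21.1 TPM, and UBXN4, FAF2 and NGLY1 fell by 3.35, 2.60 and 2.60. The VCP change was no longer called after median-of-ratios scaling (-0.18, limma, adjusted p = 0.26) or GC and length correction (-0.17, adjusted p = 0.11). Median-of-ratios scaling gave 13 lower and 7 higher, and quantile normalization 14 and 5. GC and length correction gave 5 lower and 15 higher (camera, adjusted p = 0.35), where 3419 of all 10856 genes were lower and 4087 higher. Of 33 Golgi genes, 26 fell and 3 rose (COPE, STX5 and RAB1B), with a median of -1.76, 0.63 below that of all genes, and a median GC content of 45.6% (camera, adjusted p = 0.36). The 2 scalings gave 19 lower and 10 higher, and 18 and 10. The cargo receptor TMED10 fell from 63.6 ± 8.36 to 1.49 ± 1.02 TPM, and the coatomer subunit COPB1 and the GTPase RAB1A by 4.32 and 4.22. Of 12 other OTU-family deubiquitinases, 10 fell, OTUB1 rose, and the median was -1.62, 0.50 below that of all genes, at a median GC content of 44.0% (camera, adjusted p = 0.47). Of these, 8 were lower and 2 higher after median-of-ratios scaling, 6 and 4 after quantile normalization, and 2 and 5 after GC and length correction. OTUD4 and YOD1 fell by 2.41 and 2.34, and the YOD1 call was lost after that correction (-0.19, limma, adjusted p = 0.15).

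Cell cycle genes fell almost throughout. Of 42 G1/S and replication genes, 37 fell and RFC2 rose, with a median of -1.95, 0.83 below that of all genes (camera, adjusted p = 0.039, and 0.95 with an estimated correlation) at a median GC content of 49.4%. The replication clamp PCNA fell from 144.7 ± 15.5 to 5.12 ± 5.97 TPM, and the histone mRNA binding protein SLBP and thymidylate synthase TYMS by 4.17 and 3.47. Matched lists had a median of -1.42 (adjusted p = 0.042 over the lists). The camera call was lost after median-of-ratios scaling (median -1.04 against -0.14 for all genes, adjusted p = 0.078), where 27 fell and 11 rose, and without siControl replicate 3 (adjusted p = 0.066). Quantile normalization gave 27 lower and 8 higher, and GC and length correction 24 and 3 (camera, adjusted p = 0.0039, and 0.61 with an estimated correlation). Of 47 G2/M genes, 43 fell and the kinase AURKB rose, with a median of -2.31, 1.19 below that of all genes (camera, adjusted p = 0.0073, and 0.95 with an estimated correlation) at a median GC content of 43.2%. TOP2A fell from 78.9 ± 15.9 to 2.80 ± 2.76 TPM and the mitotic kinase CDK1 from 106.0 ± 12.4 to 6.60 ± 4.56 TPM. Median-of-ratios scaling gave 36 lower and 6 higher (median -1.40), quantile normalization 42 and 2, and GC and length correction 29 and 5 (median -0.55, camera, adjusted p = 0.0011, and 0.61 with an estimated correlation). Matched lists of the G2/M genes had a median of -2.26 (adjusted p = 0.97 over the lists).

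ER protein folding genes under XBP1 and ATF6 fell in 27 of 30 cases and 0 rose, with a median of -2.35, 1.23 below that of all genes (camera, adjusted p = 0.039, and 0.95 with an estimated correlation) at a median GC content of 46.4%. The disulfide isomerase PDIA6 fell from 294.3 ± 33.1 to 19.8 ± 14.7 TPM, and the chaperones HSP90B1 and CANX fell by 3.61 and 3.43. The camera call was lost after median-of-ratios scaling (median -1.22 against -0.14 for all genes, adjusted p = 0.078), where 21 fell and 7 rose, and without siControl replicate 3 (adjusted p = 0.066). Quantile normalization gave 24 lower and 2 higher, and GC and length correction 21 and 4 (camera, adjusted p = 0.0039, and 0.71 with an estimated correlation). Matched lists had a median of -1.73 (adjusted p = 0.075 over the lists). Genes of the amino acid stress response under ATF4 went both ways, with 16 lower and 5 higher of 29 (CHAC1, DDIT3, SESN2, SLC3A2 and NUPR1) and a median GC content of 53.3% (camera, adjusted p = 0.43). After median-of-ratios scaling, 17 were higher and 7 lower, after quantile normalization 8 and 10, and after GC and length correction 15 and 9. The serine synthesis enzyme PSAT1 fell from 38.1 ± 4.61 to 1.88 ± 1.19 TPM, while the glutathione-degrading enzyme CHAC1 rose from 8.57 ± 2.23 to 33.8 ± 3.43 TPM and the stress factor DDIT3 (CHOP) from 115.5 ± 9.06 to 244.9 ± 40.3 TPM. Of 18 heat shock genes, 14 fell and HSPB1 rose, although HSPB1 was lower after GC and length correction (-0.25, limma, adjusted p = 0.018), and HSPD1 fell from 550.3 ± 43.4 to 56.6 ± 34.8 TPM (camera, adjusted p = 0.46). The heat shock list passed camera after quantile normalization (adjusted p = 0.012; 12 lower, 1 higher), and had 11 lower and 5 higher after median-of-ratios scaling and 8 and 7 after GC and length correction.

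Cytosolic ribosomal protein genes stood above the other genes. Of 48 tested, 23 rose, 14 fell and 11 were not called, with a median of 0.21, 1.33 above that of all genes (camera, adjusted p = 1.4e-07, and 0.80 with an estimated correlation). Their direction depended on the scaling, with 41 higher and 1 lower after median-of-ratios scaling and 16 higher and 18 lower after quantile normalization (camera, adjusted p = 0.96). After GC and length correction 37 were higher and 0 lower, with a median of 0.55 (camera, adjusted p = 5.8e-06, and 0.71 with an estimated correlation). RPL5 fell from 1564 ± 153 to 404.1 ± 196 TPM and RPL7 from 1973 ± 325 to 617.0 ± 190 TPM. RPL22 and RPL6 fell by 1.63 and 1.45, and after GC and length correction RPL7 and RPL22 lay at 0.33 and 0.74, while RPL5 and RPL6 lay at -0.28 and 0.13 and were not called (limma, adjusted p = 0.062 and 0.23). Matched lists, at the genes' median GC content of 51.5%, had a median of 0.10 (adjusted p = 0.69 over the lists).

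**Figure D3:**
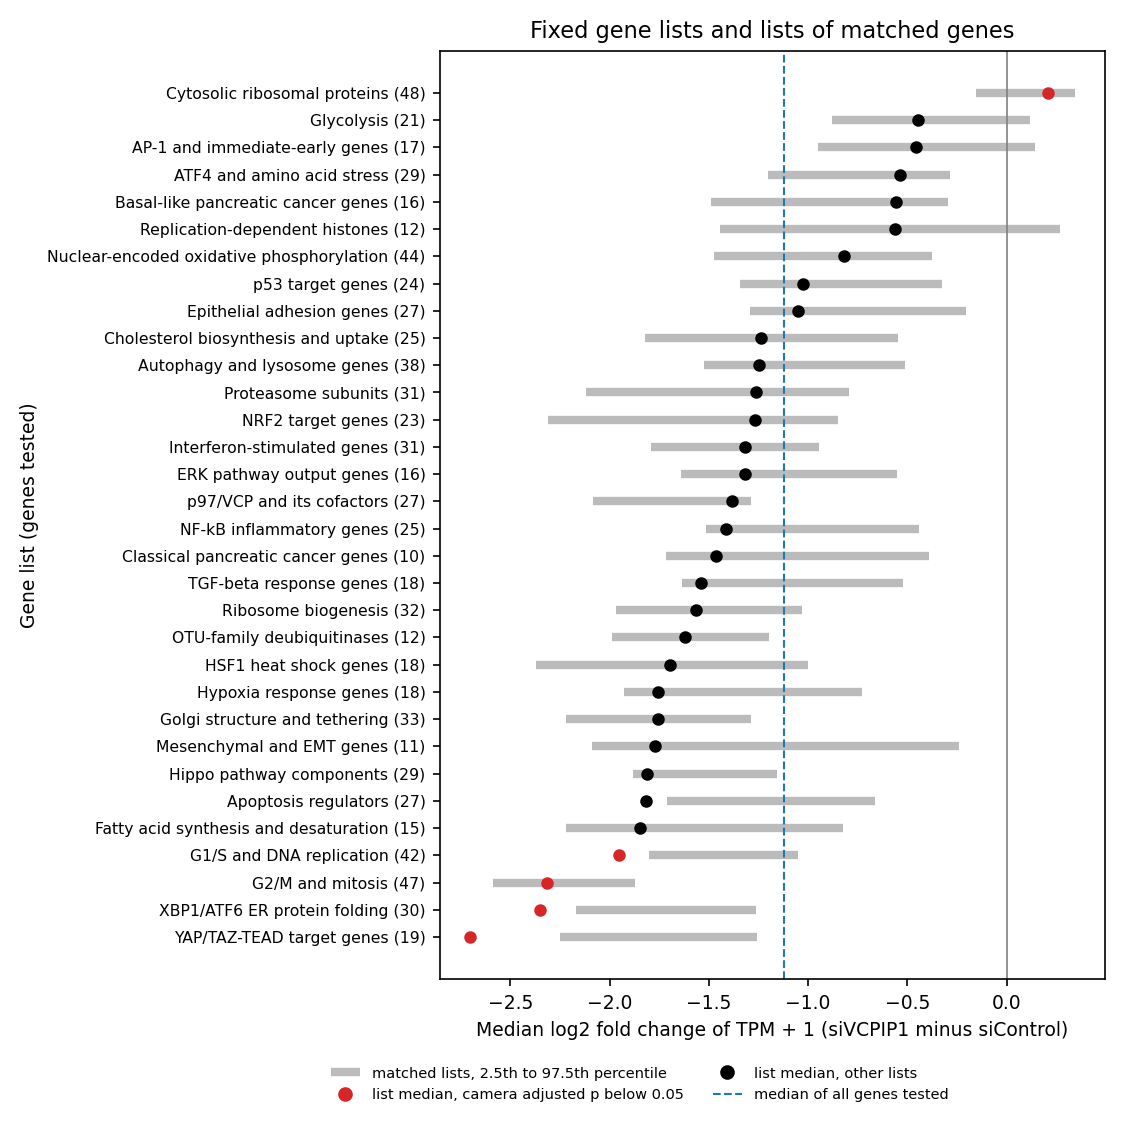
Median log2 fold change of TPM + 1, siVCPIP1 minus siControl (x axis), of the 32 lists with at least 5 tested genes (y axis, number of genes in brackets), red where camera's adjusted p with the preset correlation is under 0.05. Grey bars span the middle 95% of 10000 matched lists, and the YAP/TAZ-TEAD median of -2.70 lies below its bar of -2.25 to -1.26.

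Inflammatory and signalling lists did not pass camera (adjusted p from 0.39 to 0.84). Of 31 interferon-stimulated genes, 21 fell and 7 rose at a median GC content of 46.9%, with 15 lower and 11 higher after median-of-ratios scaling, 11 and 14 after quantile normalization and 9 and 15 after GC and length correction. IFIT1 fell from 37.7 ± 9.99 to 1.71 ± 1.08 TPM and IFI44 from 33.0 ± 3.97 to 2.44 ± 2.14 TPM. Of 25 NF-kB genes, 16 fell and 5 rose (NFKB2, IL32, RELB, SAA1 and LCN2; 6 adjusted over the list alone), and the chemokines CXCL8 and CXCL1 fell by 3.38 and 3.38. The 2 scalings gave 11 lower and 9 higher, and 10 and 9. Of 17 AP-1 and immediate-early genes, 7 fell and IER2 and JUND rose. After median-of-ratios and quantile scaling 9 were higher under each, with 4 and 3 lower, and after GC and length correction 3 were higher and 6 lower. The transcription factor MYC (58.7% GC) fell from 54.2 ± 8.08 to 4.36 ± 4.0 TPM. The transcript taken for its GC content had no 3' UTR of at least 100 nt, so 58.7% may not stand for the whole mRNA. Of 16 ERK output genes, 12 fell and ETV4 rose, with 9 lower and 4 higher after median-of-ratios scaling and 9 and 3 after quantile normalization. Of 18 TGF-beta response genes, 12 fell and TAGLN, TGFB1 and ID3 rose, with 9 lower and 6 higher, and 10 and 6, under these scalings. Of 24 p53 targets, 13 fell and 6 rose, and CCNG1 and GADD45A fell from 84.7 ± 8.06 to 10.2 ± 6.34 TPM and from 24.3 ± 4.21 to 2.24 ± 1.45 TPM. After median-of-ratios scaling, 11 p53 targets were higher and 12 lower, after quantile normalization 11 and 9, and after GC and length correction 11 and 3. Of 27 apoptosis regulators, 18 fell (19 adjusted over the list alone) and BAD, BAX, BOK and BAK1 rose, with 14 lower and 12 higher after median-of-ratios scaling, 15 and 8 after quantile normalization and 9 and 7 after GC and length correction, where BAX lay at -0.0164 and was not called (limma, adjusted p = 0.88).

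Metabolic lists did not pass camera either (adjusted p from 0.18 to 0.84), though the NRF2 targets did after quantile normalization (adjusted p = 0.033). Of 21 glycolysis genes, 12 fell and 6 rose at a median GC content of 55.6%, with 13 higher and 4 lower after median-of-ratios scaling, 9 higher and 8 lower after quantile normalization, and 9 higher and 4 lower after GC and length correction. The glucose transporter SLC2A1 fell from 140.5 ± 16.4 to 26.5 ± 12.1 TPM, and GAPDH rose from 11938 ± 1037 to 24334 ± 3632 TPM. Of 25 cholesterol genes, 15 fell and 5 rose (MVD, MVK, TM7SF2, PMVK and FDPS), with 10 lower and 11 higher after median-of-ratios scaling, 13 and 8 after quantile normalization and 8 and 10 after GC and length correction, and the epoxidase SQLE fell by 4.07. Of 15 fatty acid genes, 12 fell and AGPAT2 rose, with 9 lower and 5 higher, and 7 and 3, under these scalings. Of 18 hypoxia genes, 14 fell and ANGPTL4 rose, with 12 lower and 3 higher, and 10 and 4. Of 44 nuclear-encoded oxidative phosphorylation genes, 25 fell and 11 rose, with 14 lower and 23 higher after median-of-ratios scaling and 24 and 12 after quantile normalization, and SDHD fell by 4.10. Of 23 NRF2 targets, 17 fell, with 10 lower and 10 higher after median-of-ratios scaling, 17 and 6 after quantile normalization and 11 and 11 after GC and length correction, and NFE2L2 itself fell from 53.1 ± 11.6 to 2.51 ± 1.48 TPM.

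Among lists of cell identity (camera, adjusted p from 0.49 to 0.88), 19 of 27 epithelial adhesion genes fell and 5 rose (KRT7, KRT19, KRT18, PKP3 and KRT8). After median-of-ratios scaling 12 were lower and 12 higher, and after quantile normalization 11 and 9, where KRT8 lay at -0.12 and was not called (limma, adjusted p = 0.26). E-cadherin CDH1 fell from 28.9 ± 2.41 to 0.677 ± 0.57 TPM, while keratin KRT19 rose from 4229 ± 391 to 8365 ± 800 TPM. Of 11 mesenchymal genes, 8 fell and S100A4 and ITGA5 rose (6 and 3 after median-of-ratios scaling), and VIM fell from 3724 ± 502 to 422.2 ± 203 TPM. Of 10 genes of the classical pancreatic cancer subtype, 7 fell and TFF2 and MYO1A rose. The transcription factor GATA6 of this list (67.8% GC) fell from 5.69 ± 1.19 to 0.923 ± 0.41 TPM. Its transcript, like that of MYC, had no 3' UTR of at least 100 nt, so its GC content carries the same limit. After median-of-ratios scaling 6 of this list were lower and 3 higher, after quantile normalization 2 and 3, and after GC and length correction 4 and 5. Of 16 basal-like genes, 8 fell and 4 rose (KRT17, KRT7, LEMD1 and FAM83A; 3 adjusted over the list alone), with 5 lower and 8 higher after median-of-ratios scaling, 6 and 9 after quantile normalization and 4 and 7 after GC and length correction.

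Of the remaining lists, 20 of 31 proteasome subunits fell and 4 rose (PSMD8, PSMB3, PSMD13 and PSMB7; 2 adjusted over the list alone), with 13 lower and 14 higher after median-of-ratios scaling, 19 and 2 after quantile normalization and 8 and 16 after GC and length correction. Of 38 autophagy and lysosome genes, 26 fell and ATP6V0D1, CTSD and TFEB rose, with 18 lower and 14 higher after median-of-ratios scaling and 23 and 13 after quantile normalization. Of 32 ribosome biogenesis genes, 22 fell and 5 rose (RRP9, PPAN, BOP1, PES1 and FBL), with 17 lower and 11 higher, and 16 and 9, under these scalings, and 9 and 10 after GC and length correction. Of 12 replication-dependent histone genes, whose near-identical copies make their TPM uncertain, 7 fell and 4 rose (H2AC18, H1-2, H3C4 and H2AC8), with 1 lower and 7 higher after median-of-ratios scaling, 1 and 8 after quantile normalization and, of 11 with a known GC content, 2 and 4 after GC and length correction. H3C4 and H2AC8 lay at -0.20 and -0.10 after that correction and were not called (limma, adjusted p = 0.56 and 0.41). None of these passed camera (adjusted p from 0.36 to 0.84), though the proteasome list did after quantile normalization (adjusted p = 0.0076) and the autophagy and lysosome list after GC and length correction (0.040, and 0.71 with an estimated correlation). Matched lists of the autophagy and lysosome genes had a median of -0.96, against -1.25 for the list (adjusted p = 0.51 over the lists). Markers of other cell types were nearly absent, with 1 fibroblast, 3 leukocyte, 1 endothelial and 0 acinar or islet genes reaching the filter. LUM fell from 56.0 ± 11.7 to 2.01 ± 1.47 TPM, EGFL7 rose from 81.0 ± 18.5 to 173.7 ± 34.2 TPM, and LAPTM5 fell from 2.11 ± 0.16 to 1.12 ± 0.30 TPM, although it was higher by 0.82 after quantile normalization. Of the mitochondrially encoded mRNAs and the non-polyadenylated RNAs, 0 were among the deposited symbols, so neither list could be examined and RNA quality could not be read from them.

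The 12 largest falls by the rule included PCNA and TMED10. Integrin ITGB1 fell from 354.9 ± 34.6 to 9.12 ± 6.89 TPM (log2 fold change -5.34, SE 0.39, limma, adjusted p = 2.0e-05). The mitochondrial peroxidase PRDX3 and the actin-binding protein CAP1 fell by 5.28 and 5.27, and the protease-activated receptor F2RL1, the metalloprotease ADAM9 and the lysosomal protein LAPTM4A by 5.22, 5.13 and 4.94. The surface proteins EPCAM, of the epithelial list, and CD9 fell by 4.85 and 4.85, the cohesin subunit RAD21 by 4.85 and the cytokinesis protein ANLN, of the G2/M list, by 4.75. B2M, the light chain of MHC class I, fell from 1386 ± 191 to 97.3 ± 80.9 TPM and ACTB from 3527 ± 352 to 1341 ± 546 TPM. The ACTB, AXL, RPL7, RPL22 and RPL6 falls were not called after median-of-ratios scaling (limma, adjusted p from 0.057 to 0.36), nor those of WWTR1 and GATA6 after quantile normalization (0.11 and 0.061). All 12 falls by the rule kept their direction and call after GC and length correction, but each was smaller. These 12 genes were chosen as the largest falls in the same data, so keeping the call is not separate support. Corrected changes ran from -3.53 (CAP1) to -2.53 (TMED10), with ITGB1 at -3.03.

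The largest rises were smaller than the largest falls with TPM as deposited. After GC and length correction CXCR5 lay at 3.54, and the other rises by the rule with a known GC content at 1.08 to 2.89. The 12 falls then lay at -3.53 to -2.53. The chemokine receptor gene CXCR5 rose from 2.59 ± 2.36 to 22.7 ± 3.14 TPM (log2 fold change 2.94, SE 0.44, limma, adjusted p = 2.7e-04), and the secreted glycoprotein PAEP rose from 27.6 ± 2.54 to 124.6 ± 21.4 TPM. IER5L, CHAC1 and NBL1 rose by 1.96, 1.89 and 1.87 on the log2 scale, and CFAP73 by 2.35. CXCR5 and CFAP73 overlap BCL9L and DDX54 on the opposite strand, and IER5L overlaps the antisense genes AL158151.3 and AL158151.1 there. NBL1 overlaps MINOS1 on its own strand. With the strand setting not given, the reads of CXCR5, CFAP73, IER5L and NBL1 may not be their own. Among the falls by the rule, RAD21, CAP1 and ANLN overlap UTP23, PPT1 and KIAA0895 on the opposite strand. ITGB1 and TMED10 overlap the noncoding genes ITGB1-DT and AL049780.2 there, so the same caution holds for these falls. GGTLC2, GGT2, ATAD3C, CGB1, CGB2 and CGB5 rose by 1.85 to 2.49 on the log2 scale, but these genes share reads with near-identical paralogs and their values are uncertain. Other rises lost their call: KRT18, S100A4, PSMD13, PSMB7 and FBL after quantile normalization (limma, adjusted p from 0.061 to 0.56), and UBXN1, LCN2, JUND, PKP3, KRT8, CTSD, TFEB, BOP1 and FBL after GC and length correction (0.11 to 0.59).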

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

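The corrections for GC content and length were chosen after the data were seen, and the other alternatives before. The count of genes higher in siVCPIP1 (1646) was 4416 after median-of-ratios scaling, 4625 after quantile normalization, 4087 after GC and length correction, 3979 with that correction and a pseudocount of 0.1, and 380 with an absolute log2 fold change of at least 1. The count of genes lower (7241) was 4258 after quantile normalization, 3419 and 3350 after the 2 corrections, and 4679 with a mean of at least 5 TPM, where fewer genes were tested. Leaving out 1 library at a time gave 1245 to 1851 genes higher, 6742 to 7772 lower, a VCPIP1 change of -1.78 to -1.62, a YAP/TAZ-TEAD median of -2.83 to -2.61 (camera, adjusted p = 0.012 to 0.022), a Hippo median of -2.05 to -1.72 (0.066 to 0.12) and 3 to 5 lists called. Of the 5 lists called, 3 were left without siControl replicate 3, 3 after median-of-ratios scaling, 3 after correction with a pseudocount of 0.1, and 0 with an estimated correlation, where the YAP/TAZ-TEAD median of -2.70 had an adjusted p of 0.953. Quantile normalization called 7 (heat shock, proteasome and NRF2 gained, ribosomal proteins lost), GC and length correction 6 (autophagy and lysosome gained) and no filter 6 (Hippo gained). With no filter the Hippo median was -1.79 and passed camera (adjusted p = 0.0094). The scalings and the correction centre the libraries, which moves the gene counts toward balance. The cause of the other shifts was not tested. VCPIP1 lies under the filter of at least 5 TPM, which gives it no value.

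Directions turned for some named genes. Median-of-ratios scaling divides each library by a constant and moved the median of all genes from -1.12 to -0.14. The turns it gave follow from that upward shift. The cause of the other turns was not tested. After median-of-ratios scaling TEAD2 lay at 0.84, TEAD3 at 0.33, NUAK2 at 0.69 and LAPTM5 at 0.17, and after quantile normalization at 0.97, 0.65, 1.06 and 0.82, with KRT8 at -0.12. After GC and length correction VCPIP1 lay at 0.26, LATS1 at 0.51, NUAK2 at 0.19, RPL7 at 0.33, RPL22 at 0.74, RPL6 at 0.13, LAPTM5 at 0.71, HSPB1 at -0.25, BAX at -0.0164, H3C4 at -0.20 and H2AC8 at -0.10. With that correction and a pseudocount of 0.1, VCP lay at 0.079, NUAK2 at 0.26, RPL7 at 0.66, RPL22 at 1.27, RPL6 at 0.35, LAPTM5 at 0.60, HSPB1 at -0.31, BAX at -0.0657 and H2AC8 at -0.11. VCPIP1, LATS1 and H3C4 did not turn in that setting.

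With the replicate number as a block, limma called 1586 genes higher and 7085 lower, VCPIP1 stayed at -1.68 (adjusted p = 0.00030), 5 lists were called, and the YAP/TAZ-TEAD and Hippo medians had adjusted p of 0.028 and 0.14 (camera). Deviations of libraries with the same number correlated at 0.53, -0.27 and 0.16 across genes. Not every library correlated best with its own number: siControl replicate 2 did so with siVCPIP1 replicate 3 (0.36). Each library's difference from the others of its group also correlated with GC content, at r from -0.49 to 0.54. These correlations therefore cannot decide whether the numbers pair the libraries.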

Other observations

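The genes in the next 2 paragraphs, and the tests of library yield, transcript length, matched lists and matched genes below, with their bounds, were chosen after the results were seen, and the bounds for library yield, length and VCPIP1 were changed once after their values were known.

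Few AT-rich genes had higher TPM in siVCPIP1. Of the 2172 genes in the 20% with the lowest GC content (up to 41.8%), 2131 fell and 4 rose. Overlaps of these 4 with other genes were not examined. The 4 were the interferon-induced GTPase GBP4 (21.9 ± 2.64 to 41.0 ± 8.18 TPM, SD, n = 3; limma, adjusted p = 0.0028), the ubiquitin ligase TRIM2 (1.18 ± 0.18 to 3.27 ± 0.53 TPM), the dynein assembly factor DNAAF4 (85.8 ± 13.7 to 140.2 ± 32.1 TPM) and the zinc finger gene ZNF761 (7.43 ± 1.01 to 12.2 ± 2.97 TPM).

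Of the 2171 genes in the 20% with the highest GC content (from 59.7%), 364 fell and 1028 rose. The largest falls among those with a mean of at least 5 TPM and no overlap between the groups were of the fucosyltransferase FUT3 (9.65 ± 4.60 to 0.41 ± 0.17 TPM), the membrane protein CMTM4 (24.7 ± 1.23 to 3.03 ± 2.04 TPM) and the RNA-binding protein MEX3D (15.1 ± 3.13 to 1.39 ± 0.80 TPM; SD, n = 3).

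The first pattern is the fall of most genes, graded by GC content. With 10 splits of the 6 libraries a share under 0.05 cannot be reached: the real split (1 of 10) called 8887 genes by limma and the highest of the others 0. A GC-dependent yield of the libraries cannot be told apart from an effect of the siRNA, since each group was all of one kind: the largest slope on GC of a siControl library against the other siControl libraries was 10.07% of that between the groups, with r of -0.49, siVCPIP1 replicate 3 had a slope of -0.0247 against the other siVCPIP1 libraries (0.105 between the groups) and replicate 1 an r of 0.54, and an earlier bound of 0.2 on r would have counted this as evidence for such a yield. A yield acting evenly along each transcript is argued against by a slope on 3' UTR GC that exceeded that on coding GC by 0.02716 log2 per percent (0.0632 and 0.0360, SE 0.0017 and 0.0023), in 3886 genes whose coding sequence is at least 2 times as long, though coverage biased to the 3' end would leave it open. Loss of long transcripts is argued against among the most AT-rich genes, where the 521 longest differed from the 521 shortest in median log2 fold change by -0.0271 (bootstrap 95% interval -0.156 to 0.0996; pseudocount 0.1, siControl mean of at least 5 TPM), but it stays open among the most GC-rich, where the 588 longest lay at 0.0156 and the 588 shortest at 0.748, a difference of -0.7321 (-0.847 to -0.645).

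The second pattern is the position of the YAP/TAZ-TEAD targets below other genes. With 10 splits a share under 0.05 cannot be reached: the real split (1 of 10) gave an absolute median of 2.70 and the highest of the others 1.24. The trend with GC content, length and level is argued against as the whole cause, since 1e-04 of 10000 matched lists, the smallest share they can give, had as low a median. Matched lists are made of unrelated genes, so this share is too small for genes regulated together, and the camera call was lost with an estimated correlation (adjusted p = 0.953). An effect of the siRNA through YAP was not tested apart from these values and stays open, as does a yield of the libraries that differs by features other than those matched.

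The last pattern is the fall of VCPIP1 itself. Of the 100 genes matched to it, 24 fell to as small a share of their siControl mean (42 on the log2(TPM + 1) scale), so the trend with GC content, length and level would be enough for its fall. After GC and length correction the change depended on the pseudocount: 0.26 with 1 (limma, adjusted p = 0.066) and -0.52 with 0.1 (SE 0.16, adjusted p = 0.021). A fall of VCPIP1 beyond the trend therefore stays open.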
